A study of Schmidtea polychroa with 132 samples.

How the data were processed

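Single embryos of Schmidtea polychroa, 4 yolk samples and 1 sample labelled protist were measured by CEL-Seq with synthetic spike-in RNAs, 132 libraries in all. Per the labels' protocols, RNA was taken from single embryos with Trizol, embryos were assigned to stages 1 to 8 when collected, and libraries were treated with a duplex-specific nuclease. The authors' deposited table holds whole-number read counts per transcript model, per spike-in and for 5 HTSeq counters, not normalized. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 were used. The genome build named there belongs to Drosophila and does not match the numbered transcript models of the table, so no coordinates are given. The sources used here do not state the strand setting or the use of molecular identifiers, and the deposited list of 60 barcodes does not say which library carried which, so no batch could be taken from it. Over all libraries 63.6% of reads were counted as not aligned and 2.56% as in no feature, and 3 of the 5 counters were 0 throughout. Aligned shares given below include reads of transcripts, reads of spike-ins and reads in no feature.

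The embryos' replicate numbers used here follow the order of deposition and pair nothing. Libraries with a transcript total under 5% of the median of all libraries (16872 counts) were left out of the tests on transcripts, which removed 1 library, stage 1 replicate 1. The depth per library, the spike-in counts and the transcript counts per spike-in count were taken from the table. With no reference genome or names for the IDs, no sequence property of a transcript could be examined.

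Transcripts were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group, robust dispersion and the quasi-likelihood F test, and a Benjamini-Hochberg adjusted p under 0.05 counted as a call. The fit over stages 1 to 8 tested all stages at once, and each comparison of 2 groups used only the libraries of those groups. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are TMM-scaled CPM (library totals scaled to a common value, multiplied by edgeR's factors), given as mean and SD over libraries. The p-values weigh differences against the spread between single embryos. No capsule of origin was given for the embryos, so they were treated as independent, which could not be checked. The comparisons of consecutive stages, of yolk with stage 1 and stage 8, the distance and spread measures and the rule for named transcripts were fixed before the data were examined. That rule took, where IDs carry no names, at most 2 transcripts that rose and 2 that fell per comparison, those with the largest change among calls with at least 10 CPM on average in the higher group and detected in at least 50% of its libraries. For the protist library it took at most 2 with the highest ratio to every other library. The comparison of stage 6 with stage 4, the tests over stages 4 to 6 and over stages 1 to 3, the library sets, the protist-high transcripts and the measures of RNA content, shares of transcript sets and detected transcripts were chosen after seeing the data.

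Library sets were found by Ward clustering of log2 spike-in proportions over 26 spike-ins with at least 5 counts in 95% of libraries, divided into 4 clusters. The tests on spike-ins used the same fit on spike-in counts, with their own factors. Between libraries, distance was 1 minus Spearman's rho over 12341 transcripts, on counts as deposited for the energy distance between consecutive stages and on counts thinned to 17288 per library for the spread within a stage. The energy distance is 2 times the mean distance between stages minus the mean distances within each. Permutation tests drew 100000 permutations, or counted every split exactly where a group had fewer than 10 libraries. Tests of means were two-sided on the absolute difference, and those of the energy distance count distances as large or larger. Measures were tested only between groups that share a library set. Overlaps of calls with the yolk-high and stage-8-high sets used Fisher's exact test, two-sided, over transcripts tested in both comparisons. These share no libraries but can share a change of library set. The shares of transcript sets leave out 3 transcripts whose counts follow the spike-in counts. Binomial intervals at 95% are Wilson intervals, and the interval of a ratio of counts is exact (Clopper-Pearson). For a group with no count, the floor was 3 counts over the whole group. Transcript models were taken to share reads where the counts of a pair were equal within binomial noise over all libraries, which held for 395 pairs with 513 of 3976 transcripts that average at least 20 counts.

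Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of at least 10 counts in 50% of the libraries of a group (planned as a stricter one, though it tested more transcripts than filterByExpr in most comparisons), no library minimum and one of 25% (84358 counts, which removes 23 libraries), 1 fit over all groups, a minimum absolute log2 fold change of 1, thinned counts, leaving out each yolk library, and for the distances Pearson's r and the other treatment of depth. Those added after seeing the data were the spike-in set as a term, single sets, leaving out the stage 8 library of set C or each stage 1 library, and leaving out the transcripts that follow the spike-ins, the protist-high transcripts or the 2 libraries rich in them. Each comparison was also tested on simulated data that took the levels, library sizes and dispersion of the real libraries with 100 transcripts changed 2-fold and 100 changed 4-fold, and the share recovered was recorded. The permutation test of the energy distance was run on simulated profiles of 300 normally distributed values, with 6 libraries in each group. It gave p under 0.05 in 12 of 200 runs without a difference and in 199 of 200 with 60 values shifted. These profiles lack the sparse counts, unequal depths, group sizes and sets of the real libraries, so they do not give the power of the real tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.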

Results

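RNA was measured in 132 libraries of Schmidtea polychroa, a freshwater planarian whose egg capsules hold embryos together with separate yolk cells. The capsules were kept at 20 °C and opened over a span of 15 days of development, and each embryo was staged, frozen and sequenced on its own by CEL-Seq, a method that barcodes RNA and counts reads at the 3′ end of transcripts. The labels gave 6 embryos of stage 1, 29 of stage 2, 22 of stage 3, 10 of stage 4, 13 of stage 5, 16 of stage 6, 16 of stage 7 and 15 of stage 8, which made 127 embryo libraries. A further 4 libraries were labelled yolk and 1 was labelled protist. The deposited table held read counts for 15124 transcript models and 92 synthetic spike-in RNAs. Total transcript counts per library ranged from 16740 to 1623149, with a median of 337433.5. Median totals were 59827 in stage 1, 123967 in stage 2, 182434 in stage 3, 608300 in stage 4, 512407 in stage 5, 523738 in stage 6, 775004 in stage 7, 682548 in stage 8 and 315840 in yolk. The files do not pair transcript IDs with gene names, so lists of planarian marker genes fixed beforehand could not be used, and transcripts are given by ID.

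The proportions among the spike-ins placed the libraries in 4 sets, called A, B, C and D here, which the labels do not mention. The number of 4 was a setting of the clustering. Within a set, the mean correlation between libraries of their centred log2 spike-in proportions was 0.85 in A, 0.39 in B, 0.20 in C and 0.51 in D. Set C thus held together least, with means of -0.0354, -0.0612 and -0.0876 to sets A, B and D. Stages 1 to 3, the yolk libraries and the protist library fell in sets A and B, with 3 and 3 libraries of stage 1, 17 and 12 of stage 2, 10 and 12 of stage 3, and 1 and 3 of yolk. Set C held stages 4 to 6 and 1 library of stage 8, and set D held stage 7 and 14 libraries of stage 8. The step from stage 3 to stage 4, the step from stage 6 to stage 7 and the comparison of yolk with stage 8 therefore coincided with a change of set, and for these the set and the groups cannot be told apart. Stages 1 to 3, stages 4 to 6, and stages 7 and 8 could be compared within sets.

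The course of development was read first from how the profile of transcripts changed from stage 1 to stage 8. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 10874 of 12341 tested transcripts different among the 8 stages. Of these, 5350 (49.2%) had their highest mean level in stage 7 or 8, 3289 (30.2%) in stages 4 to 6 and 2235 (20.6%) in stages 1 to 3. The lowest mean level lay in stages 1 to 3 for 8087 of them (74.4%), and in stage 1 alone for 5587 (51.4%). Stage 1 had the lowest median total of transcript counts of the stages (59827). The levels ranked here are means of log2 CPM with a prior count of 2, which low depth can also lower. Stage and depth are therefore not separated in these counts. The median range of the stage means was 2.60 on the log2 scale. These counts span all 4 sets.

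The pairwise steps were uneven. From stage 2 to stage 3, 22 of 1716 tested transcripts changed, from stage 3 to stage 4 1559 of 4132, from stage 6 to stage 7 3940 of 7703, and from stage 7 to stage 8 553 of 8911, by edgeR. No transcript passed edgeR's threshold from stage 1 to stage 2 (426 of 2613 had an unadjusted p under 0.05, and DESeq2 called 91, and edgeR called 9 with the set as a term), from stage 4 to stage 5 (870 of 6303 and 180) or from stage 5 to stage 6 (306 of 6282 and 3). In data simulated with the counts and spread of these libraries, 4-fold changes were recovered in 1% of cases for stage 2 against stage 1, 72% for stage 5 against stage 4 and 74% for stage 6 against stage 5. For 2-fold changes the shares were 0%, 9% and 18%. The first of these zeros was therefore below what the libraries could show at 4-fold, and none of them speaks against changes of 2-fold. Transcript counts in the stage 1 libraries ranged from 16740 to 471534.

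**Figure D1:**
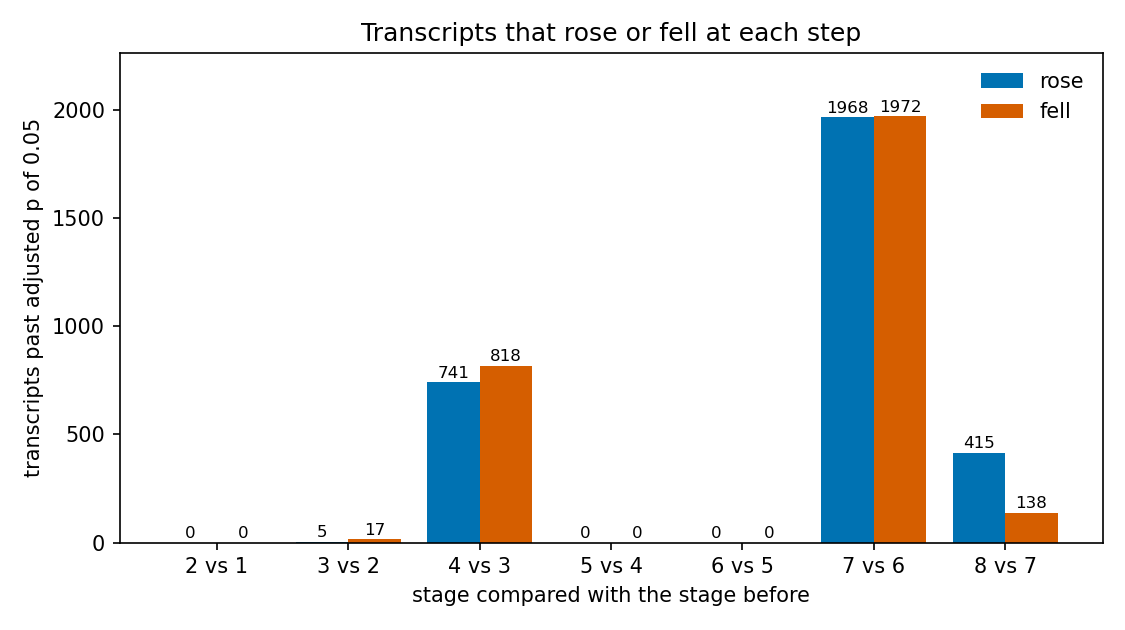
Number of transcripts past an adjusted p of 0.05 in edgeR's quasi-likelihood test at each step between consecutive stages, with rises in blue and falls in orange. The steps from stage 3 to stage 4 (741 rises, 818 falls) and from stage 6 to stage 7 (1968 rises, 1972 falls) coincide with a change of library set.

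Distances between whole profiles told steps apart in a similar order. The energy distance between consecutive stages, which is 0 on average when libraries of both stages come from 1 population, was 0.42 from stage 6 to stage 7 (permutation p = 1e-05, the smallest that 100000 permutations can give, Benjamini-Hochberg adjusted p = 3.5e-05) and 0.255 from stage 3 to stage 4 (permutation test, Benjamini-Hochberg adjusted p = 4.67e-05). It was 0.0568 from stage 7 to stage 8 (permutation test, Benjamini-Hochberg adjusted p = 3.5e-05), and 0.0564 without the stage 8 library of set C (permutation test, Benjamini-Hochberg adjusted p = 3.5e-05). Within set C it was 0.0388 from stage 4 to stage 5 (permutation test, Benjamini-Hochberg adjusted p = 0.00938). It was 0.0136 from stage 1 to stage 2 (exact permutation test, Benjamini-Hochberg adjusted p = 0.224), 0.0122 from stage 2 to stage 3 (permutation test, Benjamini-Hochberg adjusted p = 0.113) and 0.00559 from stage 5 to stage 6 (permutation test, Benjamini-Hochberg adjusted p = 0.194). The difference between stages 4 and 5 did not pass without 2 stage 4 libraries described with the protist library, at a distance of 0.0241 (permutation test, Benjamini-Hochberg adjusted p = 0.0526). Within stage 2 alone, sets A and B lay 0.0998 apart, and within stage 3 0.127, both more than the distance from stage 2 to stage 3.

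The spread between embryos was measured within each stage. The median distance between libraries of a stage, 1 minus Spearman's rho on counts thinned to 17288 per library, was 0.695 in stage 1 (quartiles 0.622 and 0.709, n = 5), 0.631 in stage 2 (quartiles 0.603 and 0.666, n = 29), 0.631 in stage 3 (quartiles 0.567 and 0.686, n = 22), 0.573 in stage 4 (quartiles 0.517 and 0.609, n = 10), 0.529 in stage 5 (quartiles 0.512 and 0.551, n = 13), 0.554 in stage 6 (quartiles 0.531 and 0.593, n = 16), 0.535 in stage 7 (quartiles 0.53 and 0.55, n = 16) and 0.535 in stage 8 (quartiles 0.520 and 0.554, n = 15). The 4 yolk libraries had a median distance of 0.513 (quartiles 0.486 and 0.535). Stages 1 to 3 each combine 2 sets, and in single sets the median was 0.629 in stage 2 (n = 17) and 0.674 in stage 3 (n = 10) of set A, and 0.593 in stage 1 (n = 3), 0.606 in stage 2 (n = 12) and 0.566 in stage 3 (n = 12) of set B. No test was made between stages.

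The ratio of transcript counts to spike-in counts was taken as a measure of embryo RNA. It is one only if each library received the same amount of spike-in RNA and counts are in proportion to RNA, neither of which was tested. The median ratio was 31.4 in stage 7 and 59.4 in stage 8. Median spike-in counts were 31811 and 11661 in these stages, and median transcript counts 775004 and 682548. On the log2 scale it rose from 4.73 ± 0.62 (SD, n = 16) to 5.78 ± 0.67 (SD, n = 15), which is 2.08-fold (permutation test, p = 0.00016, Benjamini-Hochberg adjusted p = 0.00128 over 8 tests), and 13 of 15 stage 8 libraries lay above the stage 7 mean. Without the stage 8 library of set C the rise was 2.13-fold (n = 14, permutation test, Benjamini-Hochberg adjusted p = 0.00104), above that mean in 12 of 14. In set C the log2 ratio was 2.99 ± 1.24 (SD, n = 10) in stage 4, 3.39 ± 0.72 (SD, n = 13) in stage 5 and 3.06 ± 0.88 (SD, n = 16) in stage 6, and neither step passed (permutation tests, Benjamini-Hochberg adjusted p = 0.448 for both). In sets A and B no step among stages 1 to 3 passed. The stage 2 libraries averaged -1.72 ± 1.51 (SD, n = 17) in set A and 3.17 ± 1.43 (SD, n = 12) in set B, so that ratios are comparable only within a set. The difference of stage 2 from stage 1 was 1.72 in set A (exact permutation test, p = 0.0561, n = 3 and 17) and -1.44 in set B (exact permutation test, p = 0.108, n = 3 and 12), on the log2 scale. These steps differed between the sets with p = 0.0128 (permutation test), which did not hold after adjustment (Benjamini-Hochberg adjusted p = 0.102 over 8 tests). The transcript counts include 3 transcripts that follow the spike-in counts, which together took up to 50.7% of them in stage 1, 44.8% in stage 2 and 46.6% in stage 3 of set A, at most 1.81% in set B and at most 1.44% in stages 4 to 8. With these counted as spike-ins, stage 2 averaged -2.11 in set A, its difference from stage 1 there was 2.24 (exact permutation test, n = 3 and 17, Benjamini-Hochberg adjusted p = 0.154) and the rise from stage 7 to stage 8 was 1.07 (permutation test, Benjamini-Hochberg adjusted p = 0.0012). The steps from stage 1 to stage 2 then differed between the sets with an adjusted p of 0.0646 (permutation test, Benjamini-Hochberg).

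**Figure D2:**
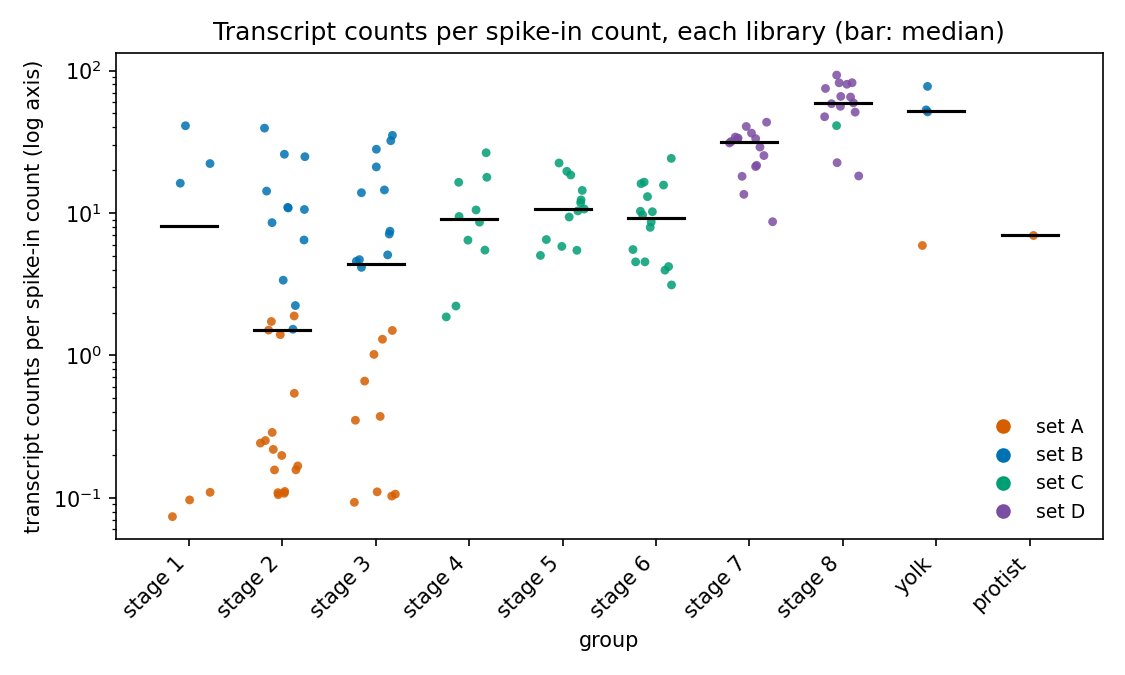
Transcript counts per spike-in count in each library on a log axis, by group and coloured by library set, with a bar at each group's median. The values of stage 8, with 1 library in set C, lie above those of stage 7 at the median (59.4 against 31.4), and set B lies above set A in stages 1 and 3 and in most of stage 2, where set A reaches 1.89 and set B begins at 1.53.

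The yolk libraries were compared with stage 8, the latest stage, to define transcripts typical of each. Here 6901 of 11073 tested transcripts differed, of which 2203 were higher in yolk and 4698 were higher in stage 8, by edgeR. FW_v1_tr_04615 was at 406 ± 220 TMM-scaled CPM in yolk (SD, n = 4) and had no count in 15 stage 8 libraries, which puts it at least 875-fold higher in yolk (edgeR adjusted p = 5.38e-11). FW_v1_tr_03847 was at 514 ± 394 CPM in yolk and 0.0708 ± 0.274 in stage 8, a log2 difference of 10.73 (SE 0.49, edgeR adjusted p = 4.58e-17). FW_v1_tr_12186 averaged 2768 ± 1798 CPM in stage 8 and had no count in yolk, at least 1332-fold lower (edgeR adjusted p = 6.11e-09). FW_v1_tr_06242 averaged 1900 ± 426 in stage 8 and had no count in yolk, at least 829-fold lower (edgeR adjusted p = 1.16e-15). Each of these held in 4 of 4 yolk libraries against the stage 8 median. The yolk libraries belonged to sets A and B and those of stage 8 to sets C and D, and 15 of 40 tested spike-ins differed as well.

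These sets of transcripts, called yolk-high and stage-8-high here, were then followed through stages 1 to 7, whose libraries had no part in defining them. The yolk-high transcripts took 70.3% ± 12.4 of transcript counts in stage 1 (SD, n = 6), 58.7% ± 17.0 in stage 2 (n = 29), 58.4% ± 18.7 in stage 3 (n = 22), 24.5% ± 5.75 in stage 4 (n = 10), 21.8% ± 6.00 in stage 5 (n = 13), 20.9% ± 4.5 in stage 6 (n = 16) and 11.7% ± 0.836 in stage 7 (n = 16). In the yolk libraries themselves they took 78.6% ± 2.44 (n = 4). The values of stages 1 to 3 combine sets that differed. The mean yolk-high share in stages 1, 2 and 3 was 61.2%, 53.6% and 50.3% in set A (n = 3, 17 and 10). In set B it was 79.5%, 65.9% and 65.2% (n = 3, 12 and 12). The stage-8-high transcripts took 11.1% ± 5.89 in stage 1, 14.3% ± 8.10 in stage 2, 15.6% ± 10.3 in stage 3, 35.7% ± 10.8 in stage 4, 43.6% ± 5.30 in stage 5, 44.4% ± 5.48 in stage 6 and 60.6% ± 1.17 in stage 7. The steps from stage 3 to stage 4 and from stage 6 to stage 7 coincide with a change of set. Within sets, no step of either share passed, the nearest being the stage-8-high share from stage 4 to stage 5, which was 7.86 percentage points higher (permutation test, p = 0.026, Benjamini-Hochberg adjusted p = 0.156 over 6 tests) and lay above the stage 4 mean in 11 of 13 libraries. This difference was 5.01 points without the transcripts high in the protist library (permutation test, Benjamini-Hochberg adjusted p = 0.274) and 3.29 points without 2 stage 4 libraries rich in them (exact permutation test, Benjamini-Hochberg adjusted p = 0.779).

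**Figure D3:**
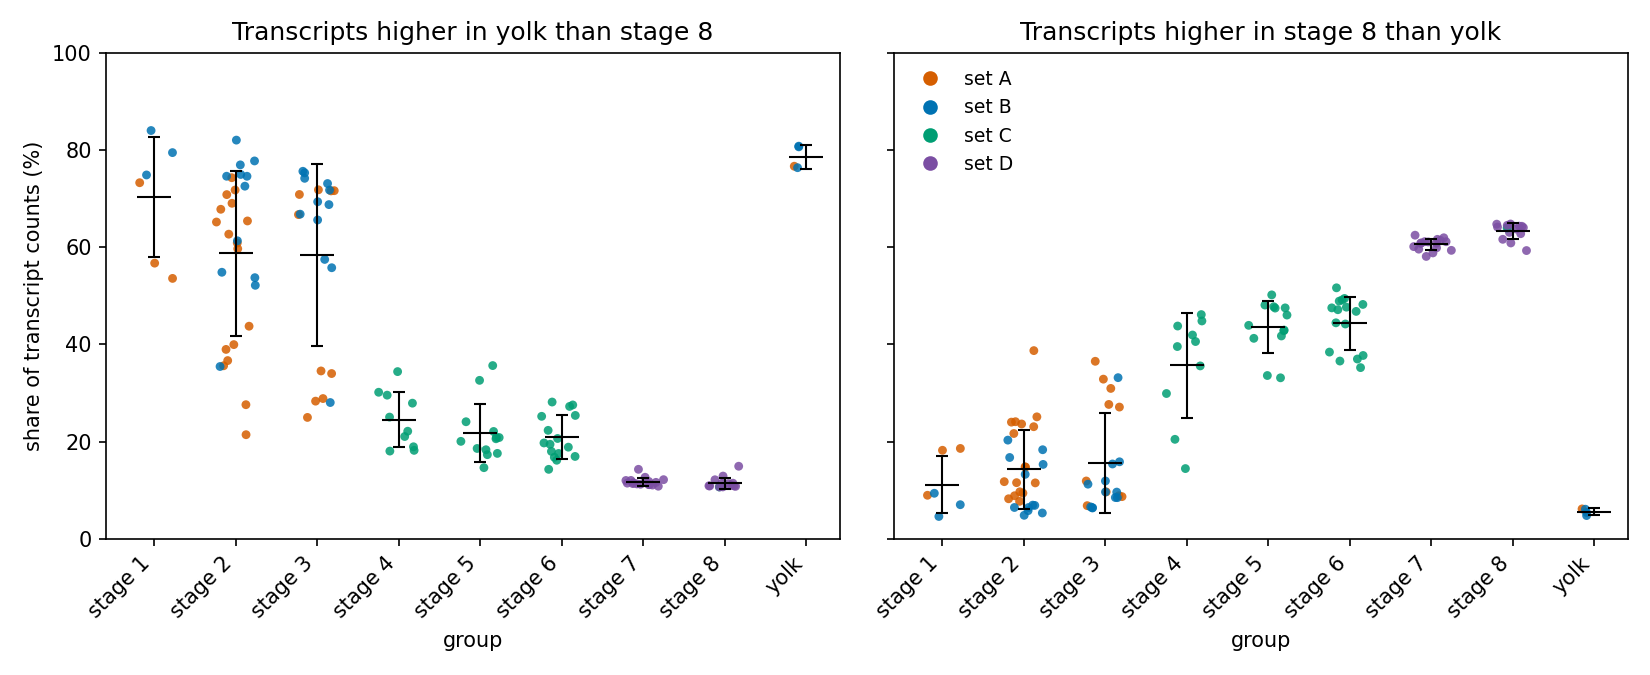
Share of each library's transcript counts taken by the 2203 yolk-high transcripts (left) and the 4698 stage-8-high transcripts (right), in percent, by group and coloured by library set, with the mean and SD of each group. Stage 8 and yolk are the groups that define both sets, and the mean yolk-high share is 70.3% in stage 1 and 11.7% in stage 7.

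No transcript passed between yolk and stage 1 in edgeR (197 of 1710 had an unadjusted p under 0.05), and DESeq2 called 13. The test had little reach, since simulated 4-fold changes were recovered in 10% of cases. Both groups were divided between sets A and B, and with the set as a term edgeR called 23. Without yolk replicate 1 the count was 48, and without stage 1 replicates 4, 5 and 6 in turn it was 20, 13 and 48.

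From stage 2 to stage 3, where each set holds both stages, 5 transcripts rose and 17 fell by edgeR. The balance turned with 1 fit over all groups (807 rises, 399 falls) and with no filter on low counts (444 rises, 418 falls). The 17 that fell together took 1.61% ± 1.65 of transcript counts in stage 2 (SD, n = 29) and 0.261% ± 0.218 in stage 3 (SD, n = 22). They exceeded 1% in 14 of 29 stage 2 libraries, 10 of them in set A and 4 in set B, and in none of the 22 of stage 3. Since the 17 were chosen for a fall between these same libraries, this contrast of stages 2 and 3 tests nothing. In stage 1 they took 0.283% ± 0.213 (SD, n = 6), and in each later stage under 0.1% on average. FW_v1_tr_12709 fell from 1350 ± 2017 to 109 ± 175 CPM, a log2 change of -3.67 (SE 0.77, edgeR adjusted p = 0.00246), with 20 of 22 stage 3 libraries below the stage 2 median. FW_v1_tr_02992 fell from 1602 ± 2031 to 165 ± 223, a log2 change of -3.32 (SE 0.67, edgeR adjusted p = 0.00228), also in 20 of 22. FW_v1_tr_08927 rose from 97.5 ± 139 to 402 ± 594, a log2 change of 1.98 (SE 0.51, edgeR adjusted p = 0.0216), above the stage 2 median in 16 of 22. FW_v1_tr_10799 rose from 80.2 ± 87.4 to 255 ± 202, a log2 change of 1.61 (SE 0.35, edgeR adjusted p = 0.00344), above it in 22 of 22, and has counts equal to those of another transcript model within counting noise. By edgeR, set A alone gave 9 calls and set B alone 0, with 145 of 2322 at an unadjusted p under 0.05 (DESeq2 was not run within sets), and a fit with the set as a term gave 23, of which 20 were among the 22. With libraries of at least 25% of the median total the 4 named transcripts missed the threshold and 6 were called.

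The step from stage 3 to stage 4 brought 741 rises and 818 falls by edgeR. The falls were mostly yolk-high transcripts, 736 of 788 that could be placed (93.4%, against 36.1% of all transcripts tested in both comparisons, Fisher's exact test, Benjamini-Hochberg adjusted p = 9.96e-318). The rises were stage-8-high in 474 of 727 cases (65.2%, against 31.7%, Fisher's exact test, Benjamini-Hochberg adjusted p = 2.76e-95), and 21 of them were yolk-high. Both this step and the comparison of yolk with stage 8 run from sets A and B to later sets, so a set difference would also give such overlaps. Transcripts are not independent of each other, so these p-values describe these libraries. FW_v1_tr_02449 averaged 296 ± 626 CPM in stage 3 (SD, n = 22) and had no count in 10 stage 4 libraries, at least 199-fold lower (edgeR adjusted p = 0.00136). FW_v1_tr_14355 fell from 103 ± 134 to 1.71 ± 2.00 CPM, a log2 change of -5.42 (SE 0.97, edgeR adjusted p = 0.00015), below the stage 3 median in 10 of 10. The largest rises, FW_v1_tr_12036 with a log2 change of 8.37 (SE 1.48, edgeR adjusted p = 0.000298) and FW_v1_tr_08800 with 6.84 (SE 1.41, edgeR adjusted p = 0.000781), belonged to the transcripts that were high in the protist library. Without 2 stage 4 libraries rich in those, the log2 changes were 0.61 (edgeR adjusted p = 0.662) and -0.11 (edgeR adjusted p = 0.952), while 1876 transcripts were called, 1406 of them shared. With RLE factors in place of TMM the median change of all transcripts was 0.55 higher on the log2 scale and 75.0% of 2212 calls were rises, against 47.5%. All stage 4 libraries differed in set from all those of stage 3, and 12 of 53 tested spike-ins were called as well. Of the 1559 calls, 49 had a change beyond that of every spike-in (3.51 on the log2 scale) and 1087 one beyond the spike-ins' 95th percentile (1.62). The median absolute log2 change was 0.32 for spike-ins against 1.12 for transcripts.

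Stages 4, 5 and 6 shared set C, the set that held together least in its spike-in proportions. Across these stages 122 of 7940 transcripts differed by edgeR, and from stage 4 to stage 6 33 rose and 70 fell of 6612. The balance turned with DESeq2 (184 rises, 147 falls) and with 1 edgeR fit over all groups (711 rises, 292 falls). Without a change of set, 30 of 33 rises were stage-8-high (90.9%, against 39.0%, Fisher's exact test, Benjamini-Hochberg adjusted p = 1.18e-09). Of 54 falls that could be placed 19 were yolk-high (35.2%, against 20.2%, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0131). Both overlaps include the 2 stage 4 libraries rich in transcripts high in the protist library. Without these libraries 1 rise and 10 falls were called, and the overlaps were not recomputed. They can therefore not be told apart from an effect of these 2 libraries. From stage 2 to stage 3, with 5 rises and 4 falls placed, no overlap passed (Fisher's exact tests, Benjamini-Hochberg adjusted p of at least 0.108). FW_v1_tr_03191 rose from 0.946 ± 1.13 (SD, n = 10) to 46.2 ± 60.8 CPM (SD, n = 16), a log2 change of 4.91 (SE 0.93, edgeR adjusted p = 0.00381), above the stage 4 median in 11 of 16 libraries. FW_v1_tr_11599 rose from 7.27 ± 11.0 to 122 ± 180, a log2 change of 3.93 (SE 0.93, edgeR adjusted p = 0.0259), above it in 14 of 16. The largest falls, FW_v1_tr_08825 at -7.25 (SE 1.43, edgeR adjusted p = 0.011) and FW_v1_tr_03218 at -6.82 (SE 1.32, edgeR adjusted p = 0.0103), were transcripts high in the protist library, and only 5 of 16 stage 6 libraries lay below the stage 4 median of FW_v1_tr_03218. Without the 2 stage 4 libraries rich in such transcripts the counts dropped to 14 across the stages and 11 from stage 4 to stage 6 (1 rise and 10 falls), FW_v1_tr_03191 still passed (edgeR adjusted p = 0.0335) and FW_v1_tr_11599 had a log2 change of 3.96 (edgeR adjusted p = 0.108). Both comparisons were chosen after the data had been seen.

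Of the 7 steps, that from stage 6 to stage 7 had the most calls in the fits of 2 groups, 1968 rises and 1972 falls by edgeR. With 1 fit over all groups it had 4538 calls, fewer than the 4786 from stage 3 to stage 4. FW_v1_tr_14913 had no count in 16 stage 6 libraries and averaged 145 ± 56.0 CPM in stage 7 (SD, n = 16), at least 331-fold higher (edgeR adjusted p = 3.41e-14). FW_v1_tr_06046 rose from 0.389 ± 1.32 to 243 ± 282 CPM, a log2 change of 8.97 (SE 0.62, edgeR adjusted p = 2.27e-15), in 16 of 16 libraries. FW_v1_tr_11052 fell from 709 ± 429 to 0.645 ± 1.17 CPM, a log2 change of -9.62 (SE 0.48, edgeR adjusted p = 1.55e-19), and FW_v1_tr_01793 fell from 686 ± 405 to 0.639 ± 1.43, a log2 change of -9.40 (SE 0.49, edgeR adjusted p = 2e-19), each below the stage 6 median in 16 of 16 libraries. The counts of these 2 equal each other within counting noise, so they were taken to share reads and stand for 1 signal. Among the rises, 1406 of 1967 were stage-8-high (71.5%, against 45.8%, Fisher's exact test, Benjamini-Hochberg adjusted p = 4.45e-157), and among the falls 412 of 1863 were yolk-high (22.1%, against 14.6%, Fisher's exact test, Benjamini-Hochberg adjusted p = 2.83e-24) and 624 stage-8-high (33.5%, against 45.8%, Fisher's exact test, Benjamini-Hochberg adjusted p = 5.92e-35). The step coincided with the change from set C to set D, and stage 8 lies almost wholly in set D, so these overlaps do not separate stage from set either. Of 43 tested spike-ins, 25 were called too (58.1%), with a median absolute log2 change of 0.45 against 0.83 for transcripts. There were 1405 called transcripts with a change beyond that of every spike-in, 834 higher and 571 lower. With RLE factors the median change was 0.32 higher on the log2 scale and 65.7% of 4022 calls were rises, against 49.9%.

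From stage 7 to stage 8, 415 transcripts rose and 138 fell by edgeR, and no spike-in of 32 was called (2 had an unadjusted p under 0.05; DESeq2 was not run on spike-ins). FW_v1_tr_09517 rose from 2.26 ± 4.52 (SD, n = 16) to 70.3 ± 56.4 CPM (SD, n = 15), a log2 change of 4.75 (SE 0.62, edgeR adjusted p = 2.24e-06), above the stage 7 median in 13 of 15 libraries. FW_v1_tr_08534 rose from 8.08 ± 13.5 to 177 ± 131, a log2 change of 4.48 (SE 0.62, edgeR adjusted p = 1.34e-05), in 15 of 15. FW_v1_tr_01754 fell from 47.5 ± 68.4 to 1.65 ± 4.43, a log2 change of -4.39 (SE 0.65, edgeR adjusted p = 1.34e-05), and FW_v1_tr_09776 fell from 156 ± 83.0 to 29.8 ± 22.6, a log2 change of -2.35 (SE 0.33, edgeR adjusted p = 9.58e-06), each in 15 of 15. Set D alone gave 504 calls, 344 higher and 160 lower, and 467 of them were among the 553. All these changes are relative to the other transcripts of a library. Over the same step the log2 ratio of transcript to spike-in counts rose from a mean of 4.73 to 5.78. Of the 138 falls, 50 reached a log2 change of 1. Smaller falls need not be declines per embryo, and larger ones can be read so only if that ratio measures embryo RNA.

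Transcripts detected per library, at 17288 counts each, averaged 2354 ± 425 in stage 1 (SD, n = 5), 2966 ± 564 in stage 2 (n = 29), 3272 ± 637 in stage 3 (n = 22), 4242 ± 749 in stage 4 (n = 10), 4793 ± 319 in stage 5 (n = 13), 4625 ± 572 in stage 6 (n = 16), 5409 ± 143 in stage 7 (n = 16), 5292 ± 190 in stage 8 (n = 15) and 3409 ± 299 in yolk (n = 4). No step within a set passed the threshold. The nearest were stage 2 to stage 3 in set B, with 404 more in stage 3 (12 of 12 libraries above the stage 2 mean), and stage 4 to stage 5, with 551 more in stage 5 (13 of 13), each with a Benjamini-Hochberg adjusted p of 0.0867 over 8 permutation tests. Without the 2 stage 4 libraries rich in transcripts high in the protist library, stage 5 had 256 more than stage 4 (exact permutation test, n = 8 and 13, Benjamini-Hochberg adjusted p = 0.199). The common depth includes the 3 transcripts that follow the spike-ins, so less of it was left for others in set A. Without these, at 8530 counts, the averages for stages 1 to 8 and yolk were 1813, 2190, 2351, 2953, 3286, 3185, 3651, 3601 and 2334, and again no step within a set passed.

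The library labelled protist, for which the labels give no further description, has no replicate and stood apart from the rest. Of its reads 8.70% aligned, and at the common depth it held 308 transcripts. FW_v1_tr_13184 had 353 counts in it and 1 in the library with the next highest CPM, a ratio of 41.9 after scaling to library totals (95% exact interval 7.47 to 1659), and FW_v1_tr_01719 had 6820 counts, 23.2 times the highest other library (95% exact interval 19.8 to 27.5). A set of 116 transcripts had at least 10 counts in it and over 10 times the median of the other libraries, and is called protist-high here. These took 97.5% of its transcript counts (95% Wilson interval 97.4% to 97.6%), 55.9% in stage 4 replicate 3 (55.7% to 56.1%) and 31.5% in stage 4 replicate 10 (31.3% to 31.8%). The next highest share was 6.17% (6.01% to 6.34%) in stage 3 replicate 5, and 11 of 131 embryo and yolk libraries lay above 1%. Such intervals, and floors for transcripts with no count, cover counting error only.

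**Figure D4:**
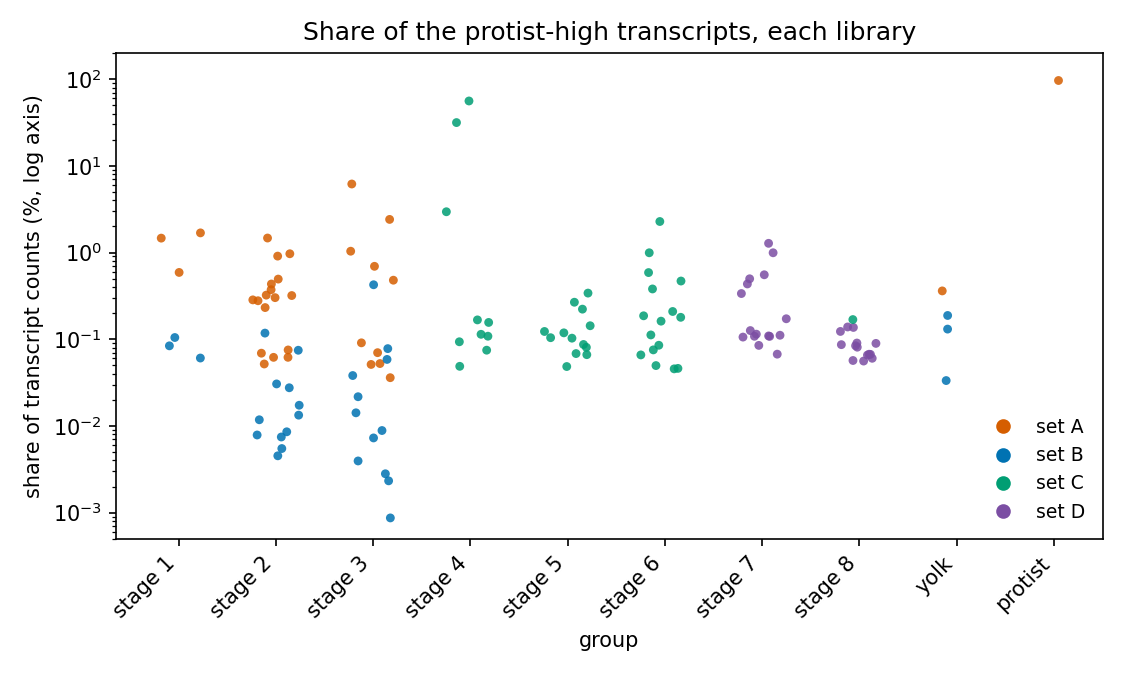
Share of each library's transcript counts taken by the 116 protist-high transcripts, in percent on a log axis, by group and coloured by library set. The protist library (97.5%) and 2 stage 4 libraries (55.9% and 31.5%) stand above the others, which reach 6.17%.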

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

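All tests in this part were chosen after the results had been seen. In 21 checks for a library far from the rest of its group, on 7 measures in each of 3 groups of 4 to 10 libraries, 3 found one, where chance gives about 1 in 20. The log2 ratio of transcript to spike-in counts in yolk replicate 1, the only yolk library in set A, was 2.56, against at least 5.68 in the other yolk libraries. Stage 1 replicate 6 had 471534 transcript counts, against at most 172074 in the other stage 1 libraries. The 10 most abundant transcripts took 25.9% of counts in stage 4 replicate 3, against at most 12.2% in the other stage 4 libraries. Signals outside the comparisons were the share of protist-high transcripts, 97.5% in the protist library, 55.9% in stage 4 replicate 3 and 31.5% in stage 4 replicate 10.

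A pair of stage 4 libraries, replicates 3 and 10, was rich in protist-high transcripts. Reads carried over from the protist library would keep its proportions, but the levels in the 2 libraries correlated with it at a Pearson r of at most 0.197 across transcripts, which are not independent replicates (upper 95% limit 0.366; 0.0622 in the other library), and with each other at 0.872. The other 8 stage 4 libraries had a share of at most 2.95%, with a median of 0.111%. RNA of a protist in the embryo samples stays open: 107 of the 116 transcripts lay above 10 times the median of the other embryo and yolk libraries in both, but the libraries were chosen for these transcripts, so this does not test it. Of all reads 18.1% and 15.3% aligned in replicates 3 and 10, against at least 22.1% in the other stage 4 libraries and 8.70% in the protist library. Yolk libraries, with few protist-high counts, aligned at 9.49% to 18.9%, so a low aligned share does not decide it. Expression by these 2 embryos themselves was not tested.

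The step from stage 3 to stage 4 coincides with a change of library set. The set difference that the spike-ins show is not excluded as the whole cause when the most extreme spike-in is the bound. Of tested transcripts 1.19%, 49 in number, were called with a change beyond it (3.51 on the log2 scale). Beyond the spike-ins' 95th percentile of 1.62 lay 1087 calls. The median absolute log2 change was 0.32 for spike-ins and 1.12 for transcripts. Whether the spike-in difference covers this step therefore depends on the bound taken. Stage and set cannot be told apart here, and development from stage 3 to stage 4 stays open, as untested.

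The step from stage 6 to stage 7 coincides with a change of library set. Of tested transcripts 18.2%, 1405 in number, were called with a change beyond the largest of any spike-in (1.73 on the log2 scale). The spike-ins thus showed no change as large as these. But the largest change among 43 spike-ins need not bound what a set difference does to 7703 transcripts. The share called was also higher for spike-ins (58.1%) than for transcripts (51.15%). The set difference that the spike-ins show is therefore not excluded as the whole cause. A set difference in embryo RNA that the spike-ins do not show, such as a different extraction, cannot be told apart from a biological change between the stages, because 0 library sets hold both. Set C also holds stage 8 replicate 12, in which yolk-high transcripts took 10.7% and stage-8-high transcripts 64.0% of counts, outside the stage 6 libraries (at least 14.3% and at most 51.7%), but this library had a part in defining both sets, 61.8% of its reads aligned against at most 44.0% in the rest of set C, and 1 library excludes nothing. Development from stage 6 to stage 7 stays among the open explanations, as untested.

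Other splits of the same libraries into groups of the same sizes were tested, 30 for the fit over all stages and 100 for each other comparison, the real one included. Chance can be excluded for the fit over stages 1 to 8 (1 split as large, real value 10874, highest other 336) and stage 4 against stage 3 (1, 1559 and 3). The same holds for stage 7 against stage 6 (1, 3940 and 943), stage 8 against stage 7 (1, 553 and 0) and yolk against stage 8 (1, 6901 and 1595). Chance is not excluded for stage 3 against stage 2 (3 splits as large, 22 and 84), whose splits were drawn without regard to set. Nor is it for stage 6 against stage 4 (2, 103 and 335) and stages 1 to 3 with the spike-in set as a term (3, 86 and 268). In these 3, other splits gave more calls than the real one, and the shares were not adjusted for the number of comparisons. For stages 4 to 6 only the real split was as large (1, 122 and 39). The splits were not repeated without the 2 protist-rich libraries, which left 14 calls there and 11 for stage 6 against stage 4. The splits say nothing about the comparisons with 0 calls by edgeR, since any of the 100 splits is as large as 0: stage 2 against stage 1 (highest other 483), stage 5 against stage 4 (8), stage 6 against stage 5 (0) and yolk against stage 1 (104); their counts at an unadjusted p under 0.05 were 426, 870, 306 and 197, and by DESeq2 91, 180, 3 and 13. The highest other split gave over 3 times the real count for stage 3 against stage 2, stage 6 against stage 4 and stages 1 to 3, which points to a structure of the libraries other than stage. Stages 2 and 3 divided by set in place of stage gave 491 calls of 1624 by edgeR, more than the 22 between the stages, for which the fit with the set as a term gave 23.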

How the results depend on the processing

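The comparisons of stage 6 with stage 4, stages 4 to 6, stages 1 to 3 with the set as a term and set B with set A, the measures within sets and all settings that concern library sets, stage 1 libraries, spike-in-tracking or protist-high transcripts were chosen after the results were seen. The fit over stages 1 to 8 kept its count within 1.5 times under every alternative run. Of the counts of calls under alternatives, 94 lay within 1.5 times the count reported and 67 did not. Of the distances, 28 kept their side of the threshold and 1 did not. Library batch as a covariate was not run, as no batch is given. No paired analysis was possible, because the embryos' numbers pair nothing and no capsule of origin was given for them. Except where a filter or thinning alters the number of transcripts tested, or a set or library is left out, the cause was not tested.

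With DESeq2 the counts of calls were 91 for stage 2 against 1, 38 for 3 against 2, 2412 for 4 against 3, 180 for 5 against 4, 3 for 6 against 5, 830 for 8 against 7, 13 for yolk against stage 1, 331 for stage 6 against 4, 305 for stages 4 to 6 and 222 for stages 1 to 3 with the set as a term. RLE factors gave 23 for stage 2 against 1. With no filter they were, in the order of the steps, 105, 862, 4313, 135, 15 and 6489, then 20 for yolk against stage 1, 401 for stage 6 against 4, 594 for stages 4 to 6 and 876 for stages 1 to 3. The filter of 10 counts gave 54 for stage 2 against 1 and 56 for stages 1 to 3, where it tested fewer transcripts, and 33 for 5 against 4, 1 for 6 against 5 and 3 for yolk against stage 1, where it tested more. With 1 fit over all groups they were 403, 1206, 4786, 301 and 147 up to stage 6 against 5, 256 for stage 8 against 7, 5 for yolk against stage 1 and 1003 for stage 6 against 4. Thinned to 17288 counts, the fits tested far fewer transcripts and gave 2, 4 and 179 up to stage 4 against 3, 189 for 7 against 6, 60 for 8 against 7, 380 for yolk against stage 8 and 13 for stage 6 against 4. A log2 fold change of at least 1 left 297 for stage 8 against 7. The 25% minimum gave 6 for stage 3 against 2, 1 for 5 against 4, 1 for yolk against stage 1 and 1383 for set B against set A (491 reported).

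The set as a term gave 9 for stage 2 against 1 and 23 for yolk against stage 1. Set B alone gave 17 for stage 2 against 1, 0 for stage 3 against 2 (edgeR, 145 at an unadjusted p under 0.05, DESeq2 not run) and 1 for yolk against stage 1, and set A alone 9 for stage 3 against 2 and 7 for yolk against stage 1, where 1 yolk library is assumed to vary like those of stage 1. Without the spike-in-tracking transcripts, or without the protist-high ones, yolk against stage 1 gave 7. Leaving out 1 library at a time gave 0 to 20 for stage 2 against 1 (20 without stage 1 replicate 3, 3 without replicate 2, 1 without replicate 5), 0 to 48 for yolk against stage 1 (48 without yolk replicate 1 or stage 1 replicate 6, 20 without stage 1 replicate 4, 13 without replicate 5) and 6307 to 6752 for yolk against stage 8. Where these are 0, edgeR gave them. Without the 2 protist-rich libraries stage 6 against 4 gave 11 and stages 4 to 6 gave 14, with the protist-high transcripts also out both gave 13, and with only these out stages 4 to 6 gave 60. The same 2 libraries left out gave an energy distance of 0.0241 from stage 4 to stage 5 (permutation test, Benjamini-Hochberg adjusted p = 0.0526), a spread of 0.523 in stage 4 and a log2 change of -0.11 for FW_v1_tr_08800 from stage 3 to stage 4, a reversed sign.

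The spread within stages 1 to 8 and yolk by Pearson's r was 0.445, 0.384, 0.402, 0.335, 0.289, 0.330, 0.296, 0.298 and 0.267. On counts as deposited it was 0.556 in stage 2, 0.529 in stage 3, 0.328 in stage 4, 0.265 in stage 5, 0.377 in stage 6, 0.209 in stage 7, 0.268 in stage 8 and 0.263 in yolk, and with the 25% minimum 0.593 in stage 1 and 0.483 in yolk. Without the spike-in-tracking transcripts, at 8530 counts, it was 0.662 in stage 2, 0.624, 0.601, 0.618, 0.611 and 0.598 in stages 4 to 8 and 0.577 in yolk. That minimum also turned the sign of steps from stage 2 to stage 3 that had not passed: detected transcripts in set A to -16.3, the log2 ratio to spike-ins to -0.81 in set A and -0.17 in set B, and the yolk-high share to 4.22 points in set A and 0.768 in set B. At 4-fold, edgeR recovered 1% of simulated changes for stage 2 against stage 1, 87%, 51%, 72%, 74%, 82% and 79% for the later steps in order, 10% for yolk against stage 1 and 42% for yolk against stage 8; depth and the number of libraries were not separated.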

Other observations

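The relations in this part were computed after the data had been seen, as a family of 12, with permutation p-values and Benjamini-Hochberg adjustment, and with the protist-high transcripts left out of both measures. Within stage 4, embryos with a higher log2 ratio of transcript to spike-in counts had a higher share of stage-8-high transcripts, with a Pearson r of 0.947 (permutation test, Benjamini-Hochberg adjusted p = 0.00032) and a Spearman rho of 0.915 (permutation test, Benjamini-Hochberg adjusted p = 0.00276) over 10 libraries. Without the 2 libraries farthest from the median ratio r was 0.882. In stage 5 r was 0.754 and rho 0.714 over 13 libraries (permutation tests, Benjamini-Hochberg adjusted p = 0.00545 and 0.019), with r at 0.855 without the 2 farthest, and in stage 6 r was 0.795 and rho 0.70 over 16 libraries (permutation tests, Benjamini-Hochberg adjusted p = 0.00078 and 0.0104), with r at 0.796. In stages 7 and 8 the relation did not pass, with r at 0.332 and 0.347 and rho at -0.0882 and -0.0357 (permutation tests, Benjamini-Hochberg adjusted p = 0.21 for both r, 0.815 and 0.901 for rho), and without the 2 farthest r was -0.377 and -0.182.

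In single stages of sets A and B, r was 0.566 for stage 2 in set A (n = 17), 0.835 for stage 3 in set A (n = 10), 0.693 for stage 2 in set B (n = 12) and 0.61 for stage 3 in set B (n = 12), each with a Benjamini-Hochberg adjusted permutation p of at most 0.0199. Of the 4 rho values, 0.412, 0.624, 0.546 and 0.671, only the last passed (permutation tests, Benjamini-Hochberg adjusted p = 0.122, 0.0914, 0.0947 and 0.0343). Without the 2 libraries farthest from the median r was 0.557, 0.855, 0.75 and 0.424. Without the 3 transcripts that follow the spike-ins, stage 3 in set A had an r of 0.836, and rho was 0.38 and 0.649 for stages 2 and 3 of set A.

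The library of stage 3 with the highest share of protist-high transcripts, replicate 5, belongs to set A, as the protist library does. Its levels of these transcripts correlated with the protist library at a Pearson r of 0.752 across transcripts, which are not independent replicates. This was not particular to replicate 5. Over libraries of stages 1 to 3, r ranged from 0.41 to 0.752 in set A and from -0.077 to 0.53 in set B. In stages 1 to 3 the median share of protist-high transcripts was 0.321% over 30 libraries of set A and 0.0142% over 27 of set B. The share of reads that aligned, spike-in reads included, had a median of 43.7% in set A, 17.6% in set B, 35.1% in set C and 64.3% in set D. Spike-ins took a median of 81.3%, 6.64%, 9.14% and 2.76% of transcript and spike-in counts in these sets. The aligned shares therefore do not compare embryo reads between sets.

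A group of 3 transcripts, FW_v1_tr_05168, FW_v1_tr_07874 and FW_v1_tr_02571, was chosen for a log2 ratio to the spike-in counts with an SD under 1 over the 132 libraries. The SD was at most 0.749 in these, 1.61 in the next transcript, FW_v1_tr_03808, and 3.27 at the median of 10043 transcripts. Together the 3 took a median of 44.2%, 18.4% and 9.45% of transcript counts in stages 1, 2 and 3 of set A, against 0.0914%, 0.30% and 0.262% in set B.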
